A study of Mus musculus with 6 samples.

How the data were processed

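Total RNA of 6 TM4 samples, 3 untreated and 3 exposed to 10 µM 4-nitrophenol for 24 h, was extracted with TRIzol, amplified and labelled with Cy3, per the labels' protocols. Groups and replicate numbers were taken from the labels. The arrays hold 62976 spots, of which 3671 are controls, and 56605 other probes. The deposited intensity values are those of Agilent Feature Extraction, version 11.5.1.1 per the file headers and 10.7 per the submitters' processing notes: a processed signal that is background-subtracted and not normalized between arrays, and the median signals of each spot and of its local background. The authors' log2 table of the same arrays has nearly the same sorted values in every column, as quantile normalization gives, and follows each array's own processed signal with a correlation across probes of 0.998 or more; its scale and normalization are read from the values and its direction is that of the signal. Every column of it has a median of 4.74.

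From these, log2 of the processed signal was averaged over the spots of a probe, without outlier spots, and each array's 75th percentile was subtracted. A probe entered if it was well above background on all 3 arrays of at least 1 group, which 28208 probes did, and a gene was represented by its brightest probe. Probe accessions were matched without versions to a RefSeq table of the GRCm38.p6 assembly, used for names only, since the file headers name another build: 33767 probes had a symbol and 22838 did not. The 21479 units tested were 13538 named genes and 7941 transcripts without a symbol here, each treated as its own unit. Where a probe was not well above background on any array of a group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

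Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all units, threshold 0.05, and a fold of at least 2 as a second criterion). Gene lists written before the data were examined (41, with 940 of 941 genes matched to a symbol) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 39 lists with at least 5 measured members; camera with an estimated correlation and fry were run beside it. The genes named are the 12 with the largest change in each direction past the threshold, filled up by the smallest p among genes with separate groups and at least a 2-fold difference, up to 4 members of each list that passed, and a fixed panel of xenobiotic, stress, estrogen receptor and Sertoli cell genes; a further item of the panel is not reported here. Predicted genes, clone names and unnamed transcripts were left out of the naming.

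Arrays were simulated with the real means and moderated spreads of the 21479 units of this comparison and 200 changed genes. There limma recovered 0.7% of genes changed by 0.5 on the log2 scale, 19.8% at 1, 96.5% at 2 and 99.5% at 3. False calls were 8.5 per run over 20 runs. The sizes were mixed within each run, and large changes ease the adjusted threshold for small ones. Recovery of small changes alone may therefore be lower. A difference between array positions was not simulated. Moderated spreads vary less between genes than raw ones, and all genes were drawn independently, so recovery on the real arrays may differ. A list of 33 genes shifted by -0.3 reached an unadjusted p under 0.05 in 20 of 20 runs and an unshifted list in 0, with genes drawn independently.

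The alternatives were normexp background correction (offset 50, on the median spot signal because the files hold no mean spot signal), quantile normalization, median centring, a percentile over probes above background on all arrays, no filter and a stricter one, a robust variance trend, array weights, blocks for slide, array position and replicate number, the median of a gene's probes, probe-level counts, the authors' values, an adjusted p under 0.1 and leaving out each array. Under slide as a random block and the robust trend, lists were tested on the moderated statistics (cameraPR). Slide 1 held untreated replicates 1 and 2, slide 2 untreated replicate 3 and PNP replicate 1, and slide 3 PNP replicates 2 and 3, so a fixed slide block rests on slide 2. All slides were scanned on 1 day. Array position 1 held untreated replicates 1 and 3 and PNP replicate 2, and array position 2 the other arrays. The packages data.table (1.17.8) and statmod (1.5.0) were also used.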

Results

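Gene expression was measured in TM4 cells, a mouse testicular somatic line that is widely used as a Sertoli cell model, after 24 h without or with 10 µM 4-nitrophenol (PNP), a phenol found in diesel exhaust and formed from some organophosphate insecticides. Each group held 3 samples, and each sample was hybridised to 1 single-colour array, so 6 arrays on 3 slides were compared. The number of arrays limits the precision. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Between 47.8% and 57.9% of the 56605 probes on an array were well above background, and no spot was saturated. Correlations across the tested genes, which are not independent replicates, ran from 0.972 to 0.986 within groups and from 0.968 to 0.983 between them.

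The comparison asked which transcripts differ between treated and untreated TM4 cells. No single gene passed the test, and the 2 gene groups that did were lower with 4-nitrophenol: DNA replication genes, with a median log2 fold change of -0.32 over 33 members, and immediate early genes of growth factor signalling, with a median of -0.35 over 26 members. Neither held with an estimated correlation between genes (limma camera, adjusted p = 0.993 for both) or with array position, the place of an array on its slide, as a block (adjusted p = 0.199 and 0.324). Sox9, a transcription factor of Sertoli cell fate, had a log2 fold change of -0.81 ± 0.23 (SE, n = 3 per group) and did not pass in limma (adjusted p = 0.303), and a second Sox9 probe had -0.04. Hmox1, Nqo1 and Ddit3, targets of oxidative and endoplasmic reticulum stress, differed by less than 1 standard error. Among genes well above background on at least 1 array of each group and at least 2-fold different with separate groups, those with the smallest p had log2 fold changes between 1.06 and 1.64 on the higher side and between -1.62 and -1.03 on the lower side.

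Of 21479 genes and unnamed transcripts tested with limma, 0 had an adjusted p under 0.05 and the smallest adjusted p was 0.107. At an unadjusted p under 0.05 there were 2134, against 1074 expected by chance, of which 1474 were higher and 660 lower with 4-nitrophenol. Of these, 537 were at least 2-fold higher and 77 at least 2-fold lower. This balance depended on the processing, with 1016 higher and 1622 lower after median centring, and 1346 and 1657 with normexp and array position as a block. Here most of the imbalance lay in transcripts without a symbol here: named RefSeq mRNAs gave 414 higher and 337 lower (103 and 26 at 2-fold), Ensembl transcripts 500 and 91 (199 and 9), and GenBank AK clones 228 and 39 (111 and 8). The groups did not overlap for 15.4% of genes, where chance gives 10%. The filter uses the groups, which favours separate groups among dim probes, and the genes of an array vary together. Over the 10 ways to split the 6 arrays 3 against 3, 62 to 3649 genes had an unadjusted p under 0.05 (limma). Neither excess over chance can therefore be read by itself as an effect of treatment. Weighting the arrays by their estimated quality (limma's arrayWeights) gave 1365 calls, 966 higher and 399 lower. Untreated replicate 1 was weighted 9.11 and the other arrays between 0.466 and 0.798. Calls with array weights, here and below, therefore rest on an untreated group dominated by 1 array. With array position as a block, limma gave 0 calls, and 93 and 18 calls in the added versions of that fit with normexp background correction and with a robust variance trend.

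Among named genes at least 2-fold different with separate groups, the 12 with the smallest p on the higher side were Cd177, Fpgt, Zfp182, Oxr1, Abhd5, Gimap8, Tvp23b, Suco, Fam126b, Sp1, Akap17b and Samd11, and none of them passed in the planned analysis (limma, adjusted p from 0.194 to 0.274). The fit with normexp and array position as a block was added after the data were seen. In it Samd11, Tvp23b, Oxr1, Abhd5, Suco, Fpgt and Sp1 passed (limma, adjusted p from 0.0192 to 0.0476). Oxr1 also passed with a robust variance trend and that block (limma, adjusted p = 0.0401). With array weights, which lean on untreated replicate 1, all 12 passed. Cd177, a neutrophil surface glycoprotein, was not well above background in the untreated cells and was at least 1.51-fold higher with 4-nitrophenol, while normexp gave a log2 fold change of 0.06. Suco had a log2 fold change of 1.64 ± 0.32 (SE), and Abhd5, the coactivator of adipose triglyceride lipase, one of 1.53 ± 0.28. Samd11 had 1.499 ± 0.32, Tvp23b 1.41 ± 0.27, and Akap17b 1.41 ± 0.30. For Gimap8 the value was 1.33 ± 0.25, for Oxr1, an oxidation resistance gene, 1.17 ± 0.21, and for the transcription factor Sp1 1.13 ± 0.22. Fpgt, an enzyme of the fucose salvage pathway, had 1.13 ± 0.19, Fam126b 1.099 ± 0.22 and the zinc finger gene Zfp182 1.06 ± 0.18. For 7 of these genes (Oxr1, Abhd5, Tvp23b, Suco, Sp1, Akap17b and Samd11) a second, dimmer probe also passed the filter, and the probes disagreed: the second probes had log2 fold changes of 0.05 to 0.36. The genes were chosen by the difference at the first probe, which by itself favours smaller values at the second. Without Cd177, the other 11 genes ran from 1.02 to 1.91 within array position 1 and from 0.94 to 1.70 within array position 2. With the slide as a block they ran from 0.45 to 1.46. That block contrasts untreated replicate 3 with PNP replicate 1, which also differ in array position. Choosing genes with separate groups fixed the sign of these differences, and the 2-fold rule favoured their size.

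By the same rule, the 12 on the lower side were Rhox3e, Hgfac, Bambi-ps1, Btnl5-ps, Plekhd1, Dio3, Cyp4a31, Arl4a, Mybph, Epop, Mt3 and Mdga2. Again none passed in the planned analysis (limma, adjusted p from 0.198 to 0.336). With array weights, which lean on untreated replicate 1, all but Arl4a passed. Rhox3e, a homeobox gene of the X-linked reproductive cluster, was not well above background on any 4-nitrophenol array and was at least 2.17-fold lower there. Dio3, the deiodinase that inactivates thyroid hormone, had a log2 fold change of -1.08 ± 0.28 (SE), and Mt3, a metallothionein, one of -1.27 ± 0.38. Hgfac, the activating protease of hepatocyte growth factor, had -1.06 ± 0.20, and Mybph, a myosin binding protein, -1.21 ± 0.34, while a second Mybph probe had 0.95. The pseudogenes Bambi-ps1 and Btnl5-ps had -1.62 ± 0.38 and -1.15 ± 0.27. Bambi-ps1, Plekhd1 (-1.03 ± 0.26), Cyp4a31 (-1.03 ± 0.27) and Epop (-1.49 ± 0.44) were well above background on 1 of the 3 treated arrays, and Arl4a (-1.24 ± 0.35) and Mdga2 (-1.38 ± 0.42) on 2. Within array position 1 the 11 genes other than Rhox3e ran from -1.56 to -0.54, and within array position 2 from -2.47 to -0.83. With the slide as a block they ran from -2.29 to -0.26. Here too the choice of genes fixed the sign of these differences and favoured their size.

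**Figure D1:**
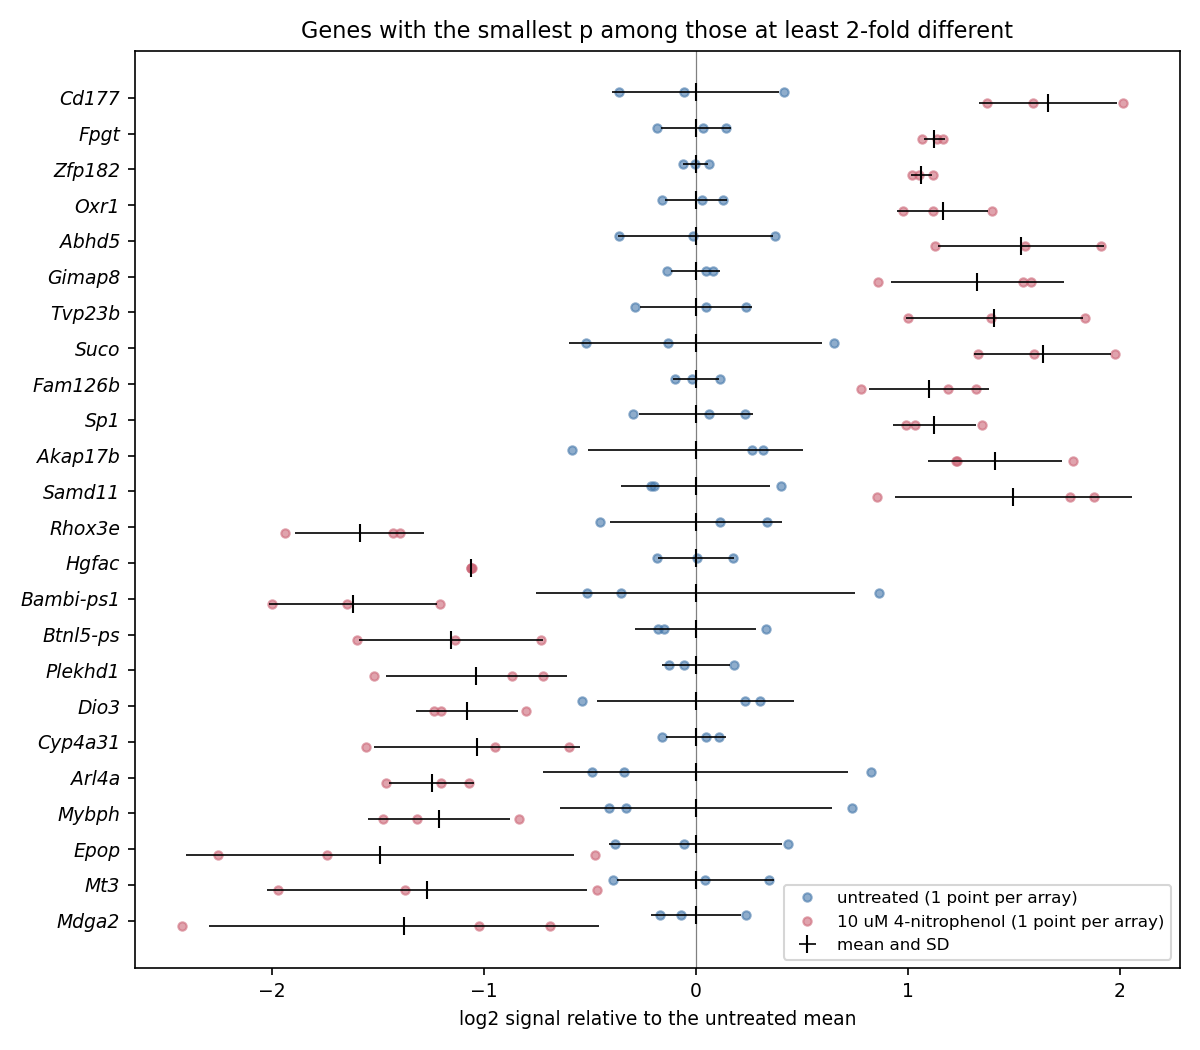
Log2 signal of the 12 named genes per direction with the smallest p among those at least 2-fold different with separate groups, relative to each gene's untreated mean (horizontal axis), with 1 point per array and bars for the mean and SD of 3 arrays. No gene passed the test.

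DNA replication genes passed as lower at the preset correlation of 0.01 (limma camera, adjusted p = 0.00302). The correlation estimated for this list was 0.408, and with it the list did not pass (limma camera, adjusted p = 0.993). Of the 10 ways to split the 6 arrays 3 against 3, 7 gave at least 2 lists at the preset correlation, the real one included. Of the 33 measured members, 0 passed the test over all genes and 0 adjusted over the list alone. Mcm3, a subunit of the replicative helicase, had a log2 fold change of -0.57 ± 0.24 (SE), E2f1, a transcription factor of S phase entry, -0.57 ± 0.24, and Gins2, a helicase cofactor, -0.41 ± 0.19. Rfc4, a clamp loader subunit, went the other way with 0.68 ± 0.22, and its second probe had -0.07. With array weights, which lean on untreated replicate 1, Mcm3, E2f1 and Rfc4 passed. Immediate early genes also passed as lower at the preset correlation (limma camera, adjusted p = 0.00529). With the correlation estimated for them, 0.248, they did not (limma camera, adjusted p = 0.993). Again 0 of 26 members were past the test over all genes and 0 adjusted over the list alone. Among them Fosb had -0.58 ± 0.22, Junb -0.54 ± 0.21, Etv4 -0.51 ± 0.26 and Jund -0.35 ± 0.21. With array position as a block the median of the DNA replication genes was -0.19 (limma camera, adjusted p = 0.199). That of the immediate early genes was -0.13 (limma camera, adjusted p = 0.324). The medians were -0.20 and -0.24 within array position 1 and -0.24 and -0.11 within array position 2. All genes had a median of -0.0645 with the block, and -0.0368 and -0.1 within array positions 1 and 2. Without untreated replicate 3, or without PNP replicate 1, 0 lists passed, and without untreated replicate 2 or PNP replicate 3 there were 6 and 7.

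The other 37 tested lists did not pass. Stress lists had medians of -0.21 for NRF2 targets, -0.06 for antioxidant enzymes, 0.07 for the unfolded protein response, -0.16 for ATF4 targets (limma camera, adjusted p = 0.0602), -0.17 for tRNA synthetases, -0.10 for heat shock genes and -0.20 for p53 targets. Core apoptosis genes were at -0.07, autophagy and lysosome genes at -0.06, and metallothionein and zinc genes at -0.02. In that last list Mt3 and Slc30a1, a zinc exporter, passed when adjusted over the list alone (limma, adjusted p = 0.0368 for both). Their log2 fold changes were -1.27 and 0.83. Over all genes neither passed (limma, adjusted p = 0.336 and 0.355). They were the only 2 such members in the 41 lists, and these p-values were not adjusted for the number of lists. Enzymes of phenol conjugation, the route by which 4-nitrophenol is cleared, had a median of -0.14 over 9 members. Aryl hydrocarbon receptor targets had 4 measured members, too few to test, with a median of 0.28.

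Metabolic lists were at -0.17 for cholesterol synthesis, -0.19 for fatty acid and lipid genes, -0.07 for fatty acid oxidation, -0.17 for glycolysis and lactate, -0.21 for hypoxia targets and -0.11 for oxidative phosphorylation. Mitosis genes had -0.06, core histones 0.04, ribosomal proteins -0.06 and epigenetic enzymes -0.06. Lists of signalling and structure had -0.08 for TGF-beta, activin and BMP genes, -0.19 for extracellular matrix, -0.13 for actin and SRF genes, -0.14 for YAP targets, -0.14 for Wnt targets, -0.23 for NF-kB and inflammation genes, and 0.04 for circadian genes. Interferon response genes had a median of 0.18 (limma camera, adjusted p = 0.129) and -0.01 with array position as a block. A negative median was found for 34 of the 39 tested lists, and 15 medians changed sign between the 5 scalings tried. The lists hold named genes only, while camera compared each with all 21479 units. Named RefSeq mRNAs as a whole had a median of -0.10, against 0.12 for Ensembl transcripts and 0.17 for GenBank AK clones. Part of the negative medians, and of the lower calls, may therefore reflect this difference between named and unnamed units. Centring each array on its median moved the median of all genes from -0.04 to -0.15.

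Among lists of reproductive function, estrogen response genes had a median of -0.08, androgen response genes 0.04, Sertoli cell markers -0.16 over 21 members, and genes of the blood-testis barrier -0.09. Markers of other testis cell types were at -0.32 for Leydig cell steroidogenesis over 7 members, -0.05 for germ cells, -0.06 for peritubular myoid cells and -0.01 for macrophages, and none passed. Endothelial markers had 2 measured members, with a median of 0.29, and were not tested. The median and the direction of the test differed in sign for antioxidant enzymes, heat shock genes, germ cell markers, core histones and androgen response genes. For these 5 lists, the unfolded protein response and epigenetic enzymes the median and the mean differed in sign.

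**Figure D2:**
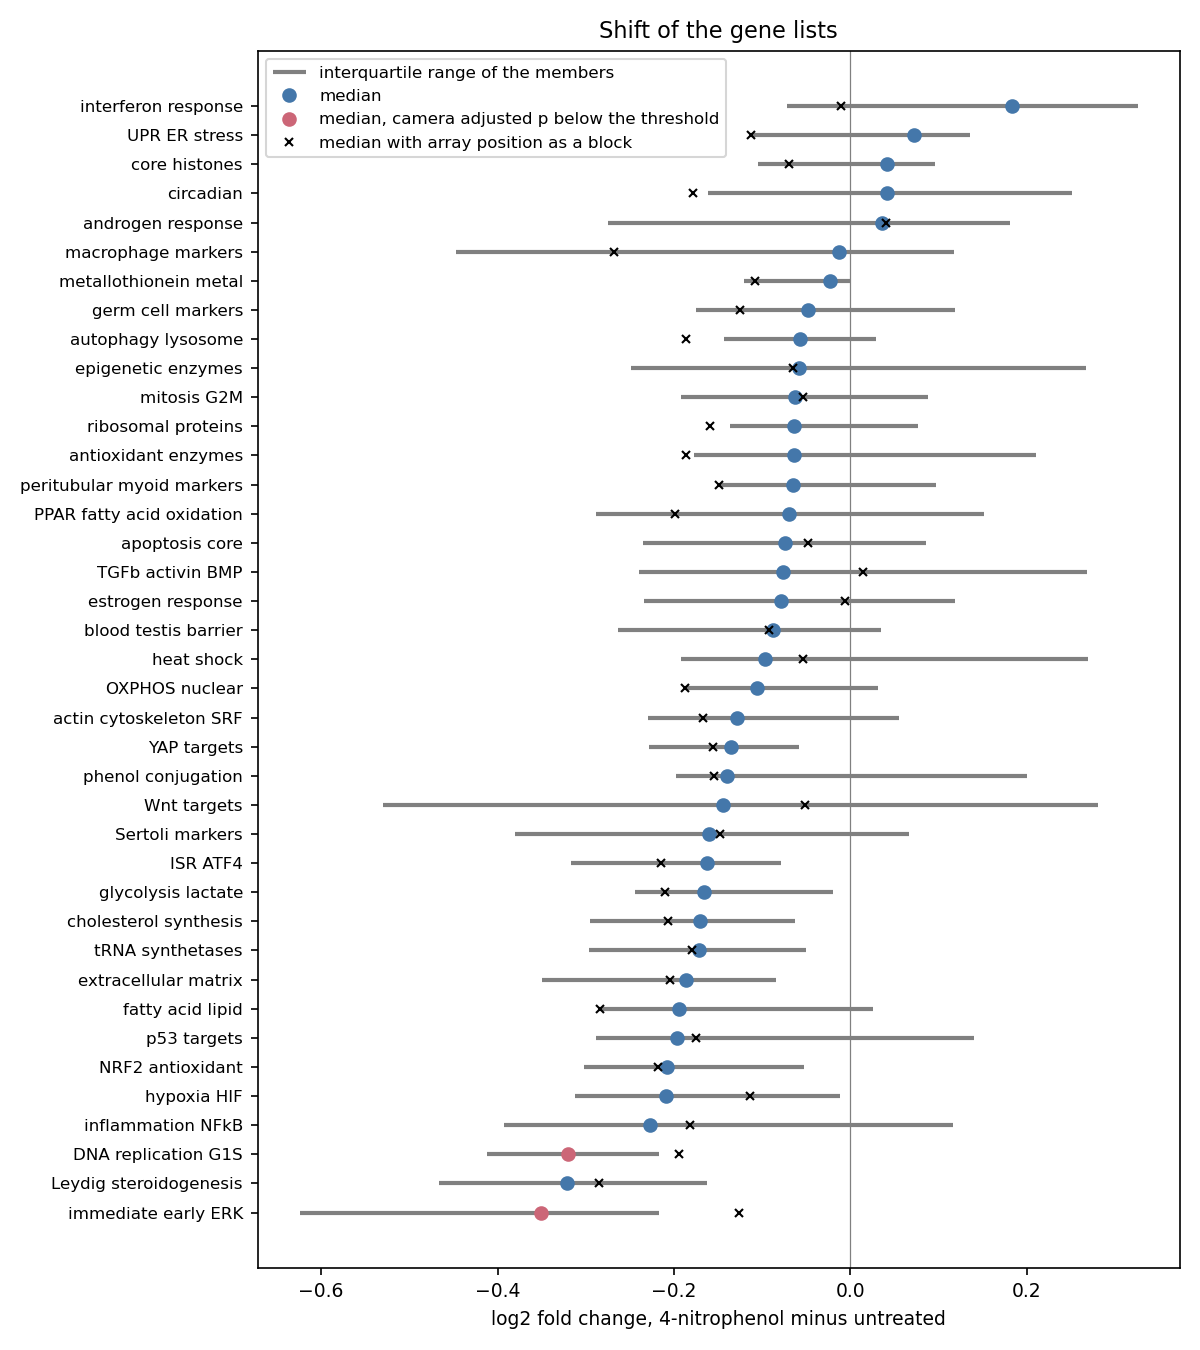
Median log2 fold change of each of the 39 tested gene lists (points, 4-nitrophenol minus untreated), with the interquartile range of its members (bars) and the median with array position as a block (crosses). The DNA replication and immediate early lists, in red, had the only adjusted p under 0.05 (limma camera, preset correlation). It was 0.993 for both with an estimated correlation. Their blocked medians of -0.19 and -0.13 lie nearer to 0, and the blocked median of all genes was -0.0645.

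Genes fixed in advance for xenobiotic and stress responses did not pass. Cyp1b1 had a log2 fold change of 0.33 ± 0.22 (SE), Nqo1 of 0.23 ± 0.37, Hmox1, the inducible heme oxygenase, of 0.17 ± 0.23, and Ddit3, a marker of endoplasmic reticulum stress, of -0.0036 ± 0.40. Cyp1a1 was not well above background on any array. The cell cycle inhibitor Cdkn1a had -0.22 ± 0.27, and its second probe 0.54. Bax, which promotes apoptosis, had -0.30 ± 0.22, with -0.466 for a second probe, and Bcl2, which opposes it, -0.08 ± 0.24, with 0.62 for a second probe.

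The estrogen receptors and Sertoli cell genes did not pass either. Esr1 and Esr2 had log2 fold changes of 0.33 ± 0.19 (SE) and 0.21 ± 0.20, and the 4 Esr1 probes ran from 0.0183 to 0.328. Sox9 had the smallest p of this panel (limma, unadjusted p = 0.00659, adjusted p = 0.303). It passed only with array weights, which lean on untreated replicate 1. Wt1 had -0.27 ± 0.23, Inhbb, a subunit of inhibin B, -0.38 ± 0.27, and the germ cell growth factors Gdnf and Kitl -0.22 ± 0.19 and 0.28 ± 0.21. The 3 Kitl probes disagreed, from 0.0898 to 1.02. Gja1, the gap junction protein connexin 43, had 0.01 ± 0.26, and its 3 probes ran from -0.285 to 0.370. Amh and Cldn11, a hormone and a tight junction protein of Sertoli cells, were not well above background on any array.

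Samples of one group differed along array position as well as between groups. The first principal component, with 34.9% of the variance, separated the arrays of position 1 from those of position 2, and the second, with 28.8%, separated untreated from treated arrays with untreated replicate 3 nearest to the treated ones.

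**Figure D3:**
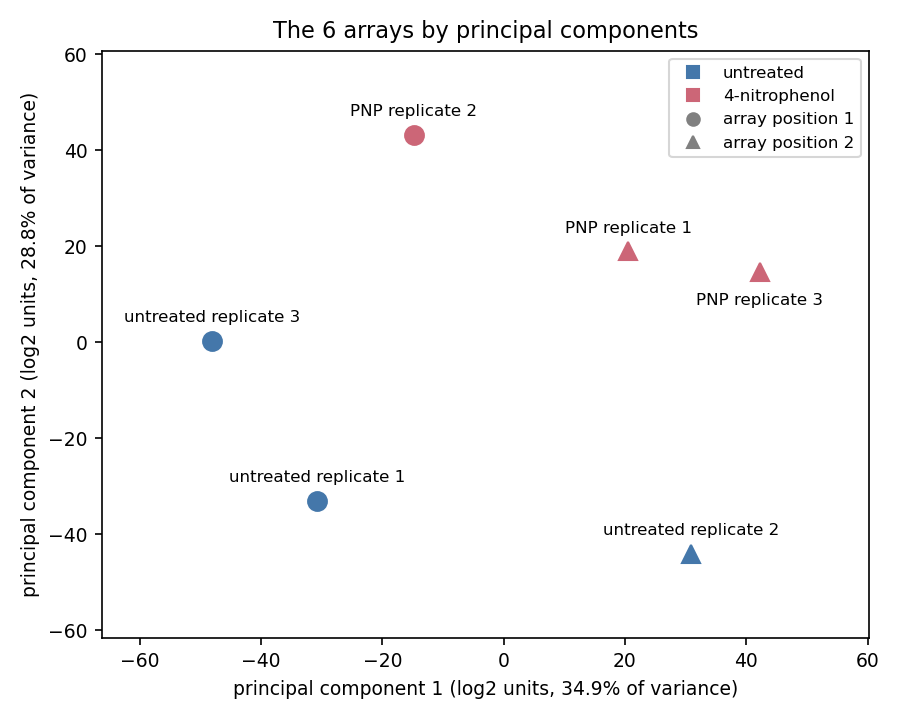
Scores of the 6 arrays on principal components 1 and 2 (log2 units), coloured by group, with circles for array position 1 and triangles for array position 2. Component 1 (34.9% of the variance) separates positions and component 2 (28.8%) separates groups.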

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

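The fits that pair a position block with normexp or with the robust trend, and those within 1 position, were chosen after the data were seen. The count of changed genes was 0 in the planned analysis and in 23 alternatives; it was 1365 with array weights, 93 with normexp and the position block and 18 with the robust trend and the position block, and at 2-fold or more 829, 66 and 18. Leaving out each array gave 0 to 0. The count at an unadjusted p under 0.05, 2134 here, was 6515 with array weights, 3425 with the robust trend and the position block, 1154 with slide as a fixed block, 1363 with the replicate block, 1044 within array position 2 and 1103 without untreated replicate 1. The replicate block gave 0 genes and 2 lists. Deviations of same-numbered arrays, which differ in position, correlated at -0.409, -0.553 and -0.406, so pairing stays open. Scan date gave no alternative, since all scans shared a day.

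The count of 2 lists became 1 without a filter, 4 with the robust trend, 8 with slide as a fixed block, 5 within array position 1, and 4 at an adjusted p under 0.1. It was 0 with array position as a block, with normexp and that block, within array position 2, with an estimated correlation and by fry. The fixed slide block compares untreated replicate 3 with PNP replicate 1, so it cannot separate treatment from array position; of its 8 lists, DNA replication, immediate early, inflammation, hypoxia and interferon genes passed in the same direction between positions. Leaving out 1 array gave 0 to 7 lists, with medians from -0.439 to -0.224 for DNA replication and from -0.559 (without PNP replicate 2) to -0.242 for immediate early genes. The interferon list passed as higher with normexp (limma camera, adjusted p = 0.00506), quantile normalization, the authors' values, the stricter filter, no filter, slide as a fixed block and without untreated replicate 2 or PNP replicate 2; it also differed between positions (median 0.46). The ATF4 list passed as lower with the robust trend (adjusted p = 0.0266 by limma's cameraPR), but not with the position block alone. It also passed with slide as a fixed block, with the median of a gene's probes, and without untreated replicate 1 or 2. It and the NRF2 list passed as lower with the robust trend and the position block, within array position 1 (1 treated array) and without PNP replicate 3. Extracellular matrix genes passed as lower with the robust trend, with slide as a fixed block, within array position 1 and without untreated replicate 2 or PNP replicate 3. With an estimated correlation none of these 4 lists passed in limma's camera (adjusted p = 0.993, and 0.999 with the position block). The cause was not tested.

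Of 1167 gene values under alternatives, 1100 kept direction and side of the threshold, 35 newly passed and 32 changed sign, all of the latter in genes that passed in no setting except Cd177 (-0.0163 with normexp and the position block). Nqo1 was -0.0883 with array position as a block and with the robust trend added, -0.0292 with normexp added, -0.0405 and -0.136 within positions 1 and 2, and -0.0148 to 0.57 leaving out 1 array. Hmox1 was -0.30 with slide as a fixed block. Ddit3 was 0.0697 with quantile normalization, 0.0719 with the percentile over detected probes, 0.42 with array weights, 0.56 with the slide block, 0.0835 with the authors' values, and -0.24 to 0.40 leaving out 1 array. Kitl was -0.0148 within position 2. Gja1 was -0.0905 with median centring, -0.27 with array weights, -0.38 with the slide block, and -0.17 to 0.19 leaving out 1 array. Cdkn1a was 0.12 with the slide block, 0.16 with the median of its probes, and -0.41 to 0.0056 leaving out 1 array. Bcl2 was 0.0662 with the position block and with the robust trend added, 0.0433 with normexp added, 0.27 with the median of its probes, 0.19 within position 1, and -0.28 to 0.037 leaving out 1 array. The cause was not tested. Probes near background limit the values of Cd177 in untreated cells, and of Rhox3e and the other genes not well above background on all treated arrays.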

Other observations

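The tests of this part were chosen after the data were seen, apart from the count of lists with array position as a block. The arrays also differed by their position on the slide, among untreated and among treated arrays. Whether the difference had the same size in both groups was not tested. With the group in the limma model, 566 genes had an adjusted p under 0.05, 239 higher and 327 lower in array position 2 (untreated replicate 2 and PNP replicates 1 and 3) than in array position 1. The count was 1173 with normexp, 900 with the stricter filter and 1392 with the robust variance trend. Some genes induced by growth factor signalling were lower in position 2. Egr1 fell by 2.16 on the log2 scale, Egr2 by 2.91 and Fosl1, an AP-1 subunit, by 2.50 (limma, adjusted p = 0.0159, 0.0174 and 0.0174). The feedback inhibitors Dusp6 (-1.60) and Spry2 (-2.22) fell too. Of the 26 measured immediate early genes, 9 passed as lower and 0 as higher. With an estimated correlation their list did not pass (limma camera, adjusted p = 0.303). Mat2a, which makes the methyl donor S-adenosylmethionine, was at -2.17. Dbp, a clock output gene, rose by 1.96, Nr1d1 by 1.21, and Tram2 by 2.72.

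Of the 39 lists, 10 passed between positions with camera's preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.303). Immediate early genes had a median of -0.62 (limma camera, adjusted p = 1.87e-08), with 9 members lower by the single-gene test, and DNA replication genes -0.26 (adjusted p = 9.7e-06). Interferon response genes had 0.46 (adjusted p = 0.00015), with Ifit3 at 1.34 and Tap1 at 1.13. Inflammation genes had -0.37, autophagy and lysosome genes 0.39, the unfolded protein response 0.40 and circadian genes 0.47.

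The difference between positions is a candidate structure of the cultures or of their handling. Faults of single probes are argued against by the correlation of 0.52 across 5151 genes between the position differences of different probes of a gene. For probes of other genes of like brightness it was 0.00688. The treatment differences of the same probe pairs correlated at 0.299 (0.27 to 0.328 over genes, which are not independent). Position was not a block there, and the groups held the positions unevenly, so part of that correlation may come from position. By itself it is therefore no evidence of a treatment effect. Noise of single arrays is argued against by the correlation of 0.594 across genes between slide 1, with untreated arrays only, and slide 3, with 4-nitrophenol arrays only. Of the 10 splits of the arrays, 1 gave as many calls as position (457 genes, against 0 in the highest other split), and 10 splits are too few to exclude chance. The design names no factor that follows position, so no biological explanation was tested, and culture density, feeding and hybridisation remain open.

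For the treatment itself, 10 of 10 splits gave at least the real 0 calls (highest other 457, the split by position) and 10 of 10 at least the real 0 at 2-fold (highest other 400), which any split does, so these counts decide nothing. At an unadjusted p under 0.05, 3 of 10 splits gave at least the real 2134 (highest other 3649, by position), and 7 gave at least the real 2 lists (highest other 9, by position). The splits are too few for a share under 0.05. With position as a block and labels exchanged within positions, the real groups gave 2940 genes, and another of the 9 arrangements gave 3770.

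The lower medians of DNA replication and immediate early genes may partly reflect array position, since position 2 held more treated than untreated arrays and the same lists were lower there. With position as a block the immediate early median went from -0.35 to -0.126 and its call ended, while the medians within positions 1 and 2 were -0.24 and -0.11. The DNA replication median went from -0.32 to -0.194 and its call ended, while the medians within positions were -0.20 and -0.24. The median of all genes was -0.0645 with the block, and -0.0368 and -0.1 within positions 1 and 2. Within position 2 the immediate early median was therefore near that of all genes. For both lists position and treatment stay open as sources of the shift.

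Ensembl and GenBank AK transcripts without a symbol here were higher with 4-nitrophenol relative to named mRNAs. The mean of these 4767 transcripts minus that of named mRNAs was -2.13, -1.99 and -2.09 on the untreated arrays. On the treated arrays it was -1.79, -1.79 and -1.88, a difference of 0.252 (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). The array position as the whole source is argued against by the difference of 0.239 ± 0.0589 (SE) with position as a block (95% interval 0.0517 to 0.426); the differences within positions, 0.319 and 0.159, have 1 array on a side and no spread of their own. Genomic DNA in the labelled samples stays open. Genomic interval probes differed by 0.0152 ± 0.0628 (SE) against named mRNAs of like brightness. Genomic DNA would reach the named mRNA probes too, so this comparison cannot decide. Brightness stays open: against named mRNAs of like brightness the difference was 0.201 ± 0.042 (SE), while normexp took the difference of medians from 0.23 to 0.09 and no filter took it to 0.03. A hypothesis for follow-up is that some probes read unspliced or alternative transcripts, which could not be tested without a genome. The 7 genes whose second probes had at most 0.36 are no evidence for it. They were chosen by the first probe, which by itself favours smaller values at the second.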
